A study of Mus musculus with 2 samples.

How the data were processed

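Small RNA libraries (insert size under 30 nucleotides, per the labels) were made from total RNA of mouse hippocampus with a multiplexed miRNA library protocol, per the labels. The deposited counts are whole numbers of reads per miRNA gene, not normalized, in 3 columns per library. The assembly mm10 and the GENCODE release M21 are named in the notes deposited with the counts. The aligner and its settings are not given in the sources used here. The columns carry no names. They were read as counts without strand, in sense and in antisense orientation, because the middle column had the larger total of the stranded columns in both libraries, a rule set before the data were examined. Another 4 rows per library name no gene (reads unplaced, with several places, on no gene, or ambiguous) and were left out of totals and tests. They held 69.5% of the reads of replicate 1 and 65.3% of replicate 2.

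All 2202 gene identifiers matched the GENCODE M21 annotation of GRCm38, which gave symbols, positions, host genes and hairpin sequences. A gene was said to share sequence where a stretch of 20 bases in the 5′ or 3′ part of its hairpin, divided at the middle, also occurs in the hairpin of another annotated miRNA gene. Copies elsewhere in the genome were not analysed here. Counts were divided by the library's total of sense reads on miRNA genes (2928141 and 3644157) to give CPM, with a pseudocount of 1 CPM on the log2 scale. At this depth 10 reads are 3.42 CPM in replicate 1 and 2.74 CPM in replicate 2. A gene was called detected with at least 10 reads in each library.

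With 1 group of 2 libraries no condition was tested, and no exact test over so few samples can reach the threshold of 0.05. Reads of each gene with a summed count of at least 10 were compared between libraries with a two-sided exact binomial test given the totals, adjusted by Benjamini-Hochberg (threshold 0.05). Intervals of ratios are exact binomial intervals at 95%. Ratios of genes with 0 reads in a library were computed against a floor of 3 counts. Counts above 0 but under this floor were kept, so ratios of such genes can point the wrong way. The common dispersion was estimated with edgeR (version 4.0.16; intercept-only design, TMM scaling, mean count of at least 10). Replicates were checked for a duplicate deposit with a chi-square over genes, which was 390 times its degrees of freedom.

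Before the data were examined, 17 lists of miRNA genes were written from general knowledge: neuron, activity-regulated, astrocyte, oligodendrocyte, microglia and leukocyte, vascular, erythroid, choroid plexus and ciliated cells, epithelial and sensory, Hox cluster, muscle, liver and endocrine, let-7, Dlk1-Dio3, Sfmbt2, mir-17-92, pluripotency and multi-copy mature sequence. None is specific to 1 cell type in gene-level counts. The multi-copy list shares 11 genes with the neuron list, 6 with let-7 and 4 with the astrocyte list. Each list's median was set against 10000 random lists of the same size, drawn from all genes for levels and matched on abundance for ratios, which needed at least 3 members with a mean count of at least 10. The percentiles describe these libraries and are not p-values. The text names the 20 genes with the highest mean CPM, the 3 most abundant members of each list, and the 5 largest ratios in each direction among called genes with a ratio of at least 2-fold and a mean count of at least 20. Further list members and the Mir9 and Mir124a genes were named after their values were seen. The genes in introns of Htr2c were taken up after the values of 3 of them, Mir1264, Mir1298 and Mir448, were seen.

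The read test was tried on simulated counts with the real totals and counting noise only (Poisson), where 473 genes were tested. It recovered 60%, 78%, 88% and 94% of genes changed by 1.2, 1.5, 2 and 4-fold, and called 2.55% of unchanged genes. These rates do not carry over to replicates that vary beyond counting noise, as the 2 real libraries did. The acceptance limit for 4-fold changes was set to 90% after the first run had fallen short of a stricter one. Simulated coefficients of variation of 0.1, 0.3 and 0.5 came back as 0.0914, 0.309 and 0.520. Alternatives were counts without strand, TMM and DESeq2 (version 1.42.0) scaling, totals without the most abundant gene, other filters and detection limits, a pseudocount of 0.1, leaving out either replicate, and leaving out the multi-copy genes. The GC correction, on the GC content of the whole hairpin, and the thinning of replicate 2 were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.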

Results

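MicroRNAs (miRNAs), short RNAs that repress messenger RNAs by base pairing, were profiled by small RNA sequencing in the hippocampus of female B6CASTF1/J mice, the F1 hybrids of C57BL/6J and CAST/EiJ, at 36 days of age. The series held 2 libraries of total RNA, named biological replicates 1 and 2 by the labels, which formed 1 group. No treatment, age or tissue was contrasted. The comparisons below describe which miRNA genes held the most assigned reads and how far the 2 libraries differed. The labels give both samples different biosample entries and the same donor entry. Whether they came from separate animals is therefore not settled by the labels, and the spread between them may be technical in part. Values are counts per 1000000 reads assigned to miRNA genes (CPM), given as mean ± SD with n = 2 unless stated otherwise.

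Of 9595913 reads in the count table of replicate 1, 2928141 (30.5%) were assigned to a miRNA gene in the sense orientation, and of 10489588 reads in replicate 2, 3644157 (34.7%) were. Reads with several equally good places in the genome made up 38.9% and 45.8%, unplaced reads 26.8% and 14.7%, and reads placed once but on no annotated miRNA gene 3.75% and 4.69%, in replicates 1 and 2. For reads placed once, a count of 0 was taken to allow up to 3 counts, which are 1.02 CPM in replicate 1 and 0.823 CPM in replicate 2. These limits do not bound genes whose reads have several places. Reads carried no molecular identifiers that were used here, so these limits and all intervals cover counting error only.

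**Figure D1:**
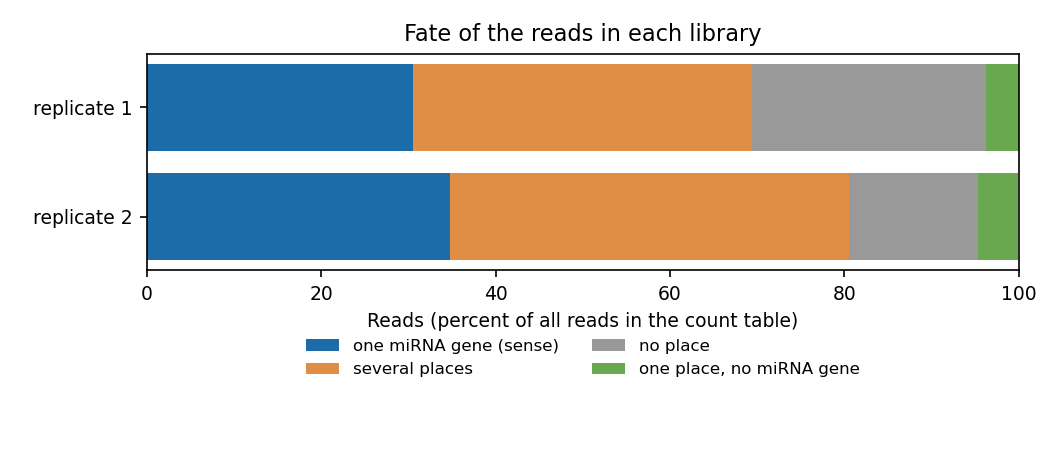
Percent of all reads in each library's count table (x axis) by where they were placed, 1 bar per library. Reads with several places form the widest part in both libraries, 38.9% in replicate 1 and 45.8% in replicate 2, ahead of reads assigned to a miRNA gene, 30.5% and 34.7%.

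Among reads assigned to miRNA genes, the let-7 family, miRNAs that are high in differentiated tissue, held a larger share than any other list. Its 13 genes held 42.5% of assigned reads in replicate 1 and 35.8% in replicate 2 (39.1% ± 4.68, SD, n = 2). Reads with several places, 1.28 and 1.32 per assigned read in replicates 1 and 2, are outside these shares and ranks. Shares and ranks in the tissue may therefore differ, since miRNAs with several gene copies can lose reads. Mirlet7g was the most abundant gene at 120442 ± 30206 CPM, followed by Mirlet7b at 106053 ± 4753 CPM and Mirlet7i at 75643 ± 9909 CPM. Mir139 reached 73904 ± 24342 CPM, Mirlet7d 46709 ± 7117 CPM and Mir127, a gene of the imprinted Dlk1-Dio3 region, 41981 ± 6116 CPM. The 10 most abundant genes took 57.6% ± 0.273 of the reads, the first 20 took 68.8% ± 0.109 and the first 100 took 95.5% ± 0.0397 (SD, n = 2).

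The order within the leading genes was not fixed by these libraries. Mirlet7g held 14.2% of assigned reads in replicate 1 (exact Clopper-Pearson 95% interval 14.1% to 14.2%) and 9.91% in replicate 2 (9.88% to 9.94%), where Mirlet7b, at 10.9%, stood above it. Mir744, in an intron of Map2k4, was at 38161 ± 287 CPM, Mirlet7e at 27756 ± 616 CPM, Mir99a at 24159 ± 9146 CPM and Mir23b at 20770 ± 475 CPM. The remaining genes of the first 20 were Mir191, Mir151, Mir126a, Mir652, Mir132, Mir382, Mir433, Mir137, Mir324 and Mir330, with means from 13048 CPM for Mir191 down to 9493 CPM for Mir330. Mir652, in an intron of Tmem164, differed least among the 20 (11407 ± 10.9 CPM). Of the 20, 3 genes (Mirlet7e, Mir191 and Mir126a) lie opposite another annotated miRNA gene and were countable only because the strand was used. Counted without strand, Mirlet7e and Mir191 had 0 reads in both libraries.

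**Figure D2:**
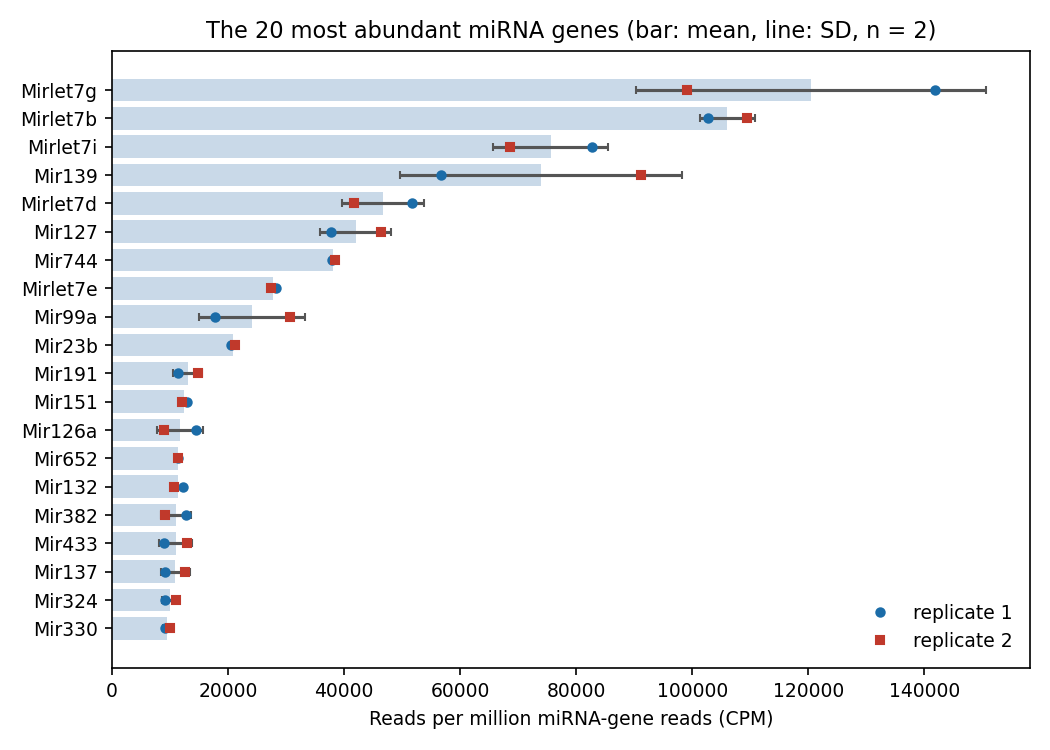
Levels of the 20 most abundant miRNA genes in CPM on a linear axis, with bars for the mean of both libraries, lines for the SD (n = 2) and a symbol per library. Mirlet7g leads at 120442 CPM on average but only in replicate 1, and the replicates of Mir652 nearly coincide.

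The gene with the highest mean, Mirlet7g (ENSMUSG00000065440.1), lies on chromosome 9 from 106178840 to 106178927 on the plus strand (assembly mm10), in an intron of Wdr82. Its annotated hairpin of 88 bases reads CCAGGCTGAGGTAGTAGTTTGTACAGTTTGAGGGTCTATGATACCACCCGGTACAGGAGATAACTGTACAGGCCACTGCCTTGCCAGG. Counts were per hairpin gene, so the mature arms of a hairpin were not told apart. Mirlet7b lies on chromosome 15 from 85707319 to 85707403 in an exon of the noncoding gene Lncppara, and Mir139 on chromosome 7 from 101475376 to 101475443.

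Of 2202 annotated miRNA genes, 376 (17.1%) had at least 10 reads in both libraries. A further 11 reached that minimum in replicate 1 alone and 43 in replicate 2 alone, the deeper library. No read was assigned to 1479 genes. Of all annotated miRNA genes, 831 share a stretch of at least 20 bases with another in both hairpin parts, and 256 in a single part. For such genes few or no reads do not show absence from the tissue, because reads with several places were counted apart.

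Gene lists set down in advance placed neuronal and imprinted miRNAs among the abundant ones. Of 14 genes of neuron-enriched miRNAs, 11 were detected, led by Mir137 (10871 ± 2488 CPM), Mir128-1 (7474 ± 4452 CPM) and Mir138-1 (4780 ± 1808 CPM). Mir128-1 and Mir138-1 are also on the multi-copy list, so their per-gene levels are uncertain. In the Dlk1-Dio3 cluster, maternally expressed miRNAs of an imprinted region on chromosome 12, 49 of 53 genes were detected. The cluster held 12.01% and 12.91% of the reads of replicates 1 and 2. Mir127, Mir382 (10942 ± 2576 CPM) and Mir433 (10934 ± 2921 CPM) led its genes. Among miRNAs known to respond to neuronal activity, 4 of 4 genes were detected, with Mir132 at 11395 ± 1073 CPM, Mir485 at 2025 ± 139 CPM and Mir134 at 560 ± 25.6 CPM.

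Glial and vascular miRNAs were also present. All 10 genes of the astrocyte list were detected, led by Mir29a (9014 ± 873 CPM), Mir22 (3738 ± 1547 CPM) and Mir29c (1164 ± 824 CPM). In the oligodendrocyte list 4 of 5 were detected, led by Mir23a (8146 ± 186 CPM), Mir219a-2 (2178 ± 1486 CPM) and Mir338 (1756 ± 504 CPM). Mir219a-2 is also on the multi-copy list, so its per-gene level is uncertain. The vascular list had 4 of 9 genes detected, with endothelial Mir126a at 11743 ± 3922 CPM, Mir143 at 5571 ± 1174 CPM and Mir145a at 194 ± 20.4 CPM. Of 8 genes of microglia and leukocytes, 4 were detected, led by Mir150 (1022 ± 294 CPM), Mir146 (610 ± 90.9 CPM) and Mir142 (61.1 ± 5.22 CPM). In the mir-17-92 list of proliferating cells, 9 of 15 genes were detected, led by Mir93 (1943 ± 410 CPM), Mir17 (860 ± 119 CPM) and Mir106b (546 ± 135 CPM). Repeated miRNAs of the Sfmbt2 list had 8 of 82 genes detected, led by Mir467d (817 ± 213 CPM), Mir669c (332 ± 9.38 CPM) and Mir467e (328 ± 24.3 CPM). Many of these are near-identical copies, so a lack of reads does not show absence.

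Lists written as checks of the dissection, of blood and of other organs ranged from undetected to moderate levels. Of 14 pluripotency genes, 0 were detected, and the list held 1 read in replicate 1 and 4 in replicate 2. The red blood cell list had 3 of 5 genes detected, led by Mir451a (654 ± 544 CPM), Mir144 (86.4 ± 40.6 CPM) and Mir486 (17.1 ± 7.16 CPM). Of 6 Hox cluster genes, miRNAs of hindbrain and spinal cord, 3 were detected, with Mir10b at 26.3 ± 15.9 CPM, Mir10a at 20.1 ± 3.52 CPM and Mir196b at 18.03 ± 4.93 CPM. The muscle, liver and endocrine list had 3 of 12 genes detected, namely Mir375 (243 ± 170 CPM), Mir206 (204 ± 42.6 CPM) and Mir122 (40.9 ± 4.24 CPM). The choroid plexus and ciliated cell list had 4 of 7 detected, led by Mir204 (1347 ± 1067 CPM), Mir34c (433 ± 17.4 CPM) and Mir449a (102 ± 30.8 CPM). The epithelial and sensory list had 4 of 8 detected, with Mir183 (68.1 ± 83.3 CPM) and Mir200b (26.9 ± 19.7 CPM) highest among them. Mir182 had the highest mean of that list (71.0 ± 97.1 CPM) but only 7 reads in replicate 1, under the detection minimum. The medians of 13 of the 17 lists lay above the 97.5 percentile of random lists in both libraries, a low bar because most annotated miRNA genes had no read.

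Several miRNAs known as abundant in brain had few counts. Mir124a-1, Mir124a-2 and Mir124a-3 had 8, 4 and 4 reads in replicate 1 and 8, 0 and 1 in replicate 2, and Mir9-1, Mir9-2 and Mir9-3 had 33, 4 and 324 in replicate 1 and 62, 2 and 480 in replicate 2. All 6 share a stretch of at least 20 bases in both the 5′ part and the 3′ part of the hairpin with another annotated miRNA gene. The multi-copy list, whose mature sequence comes from several hairpins, had 41 of 56 genes detected, led by Mir128-1, Mir138-1 and Mirlet7f-2 (3870 ± 396 CPM). Per-gene levels of its members are uncertain, because reads with several places were counted apart. The hairpin of Mir9-1 has 89 bases and reads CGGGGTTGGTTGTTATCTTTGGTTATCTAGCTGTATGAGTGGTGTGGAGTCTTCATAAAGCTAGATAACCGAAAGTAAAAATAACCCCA.

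The 2 libraries were alike in rank and differed in detail. Across 399 genes with a mean count of at least 10, Pearson's r of log2(CPM + 1) was 0.973 and Spearman's rho 0.966; these are correlations across genes, which are not independent replicates. Over 295 genes with a mean count of at least 50, the log2 ratio of replicate 2 to replicate 1 had an SD of 0.86, the median difference was 1.27-fold, and 256 genes (86.8%) lay within 2-fold. The biological coefficient of variation from edgeR was 0.382. A two-sided exact binomial test on the reads with Benjamini-Hochberg adjustment called 275 of 474 genes, 150 higher in replicate 2 and 125 higher in replicate 1. The direction of the majority was not fixed, with 135 against 133 under TMM scaling and 126 against 142 with totals that leave out the most abundant gene. This test compares the 2 libraries, not conditions, and takes counting error as the only noise. Of the 275, 140 differed by less than 1.5-fold, and 80 differed by at least 2-fold.

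Mir182 and Mir183, of a miRNA cluster known from sensory cells, and miRNAs of the serotonin receptor gene Htr2c were higher in replicate 2. Mir182 had 7 reads in replicate 1 and 509 in replicate 2, a ratio of 58.4-fold (exact 95% interval 28.2 to 146). Mir183 was 13.8-fold higher (9.35 to 21.1). Mir1298 was 17.7-fold higher (15.7 to 20.0) and Mir448 9.54-fold higher (6.64 to 14.2), and both lie in introns of Htr2c. Mir301, in an intron of Ska2, was 6.20-fold higher (5.57 to 6.92). Mir1298 lies on chromosome X from 147064905 to 147065002 on the plus strand, and its hairpin of 98 bases reads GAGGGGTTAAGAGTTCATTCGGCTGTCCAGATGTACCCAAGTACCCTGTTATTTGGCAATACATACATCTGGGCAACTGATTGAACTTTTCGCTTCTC.

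Higher in replicate 1 were Mir31 (9.70-fold, exact 95% interval 8.60 to 10.97), Mir107 (5.18-fold, 5.01 to 5.36), Mir298 (4.03-fold, 3.88 to 4.18), red blood cell Mir451a (3.85-fold, 3.58 to 4.14) and Mir103-2 (3.76-fold, 2.68 to 5.37). Mir107 and Mir103-2 lie in introns of Pank1 and Pank2, share stretches of at least 20 bases with each other, and are uncertain as single genes. These are differences between single libraries, with no replicate behind either side.

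**Figure D3:**
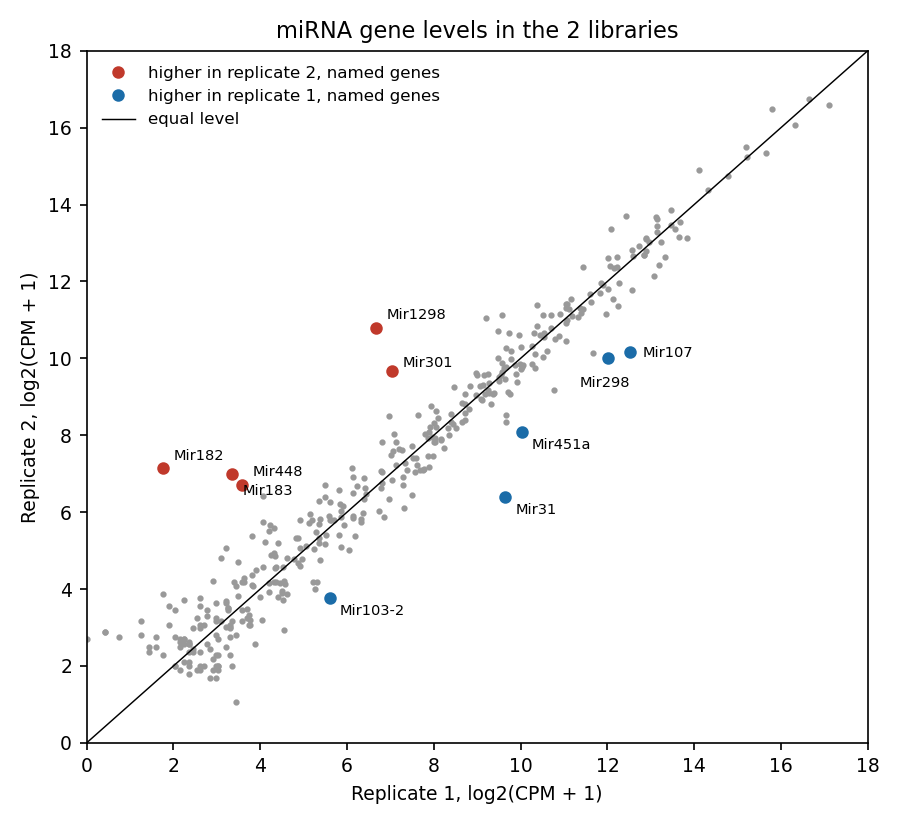
Levels of miRNA genes with a mean count of at least 10 in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1), with the line of equal level. The 5 named genes on each side lie away from the line, Mir182 the farthest at 58.4-fold, while Pearson's r over 399 genes was 0.973.

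Marker lists moved apart between the libraries. Medians of 5 of 16 lists lay outside the central 95% of random lists matched on abundance. Chance would give 0.8 on average if members varied independently. They did not over all pairs of genes of the same number, which differed less in log2 ratio than abundance-matched pairs (0.53 against 0.78). Pairs among let-7 genes of any letter are included, and the value without them was not computed. The chance number can therefore be higher, and the percentiles can be too extreme for lists built of such families. List members that lie close together in the genome, such as Mir182 and Mir183, may vary together too, which the percentiles do not take into account. The epithelial and sensory list was higher in replicate 2, with a median log2 ratio of 1.81 (percentile 99.97) and 5 of 6 measured genes called, all 5 higher in replicate 2; 6 passed when adjusted over the list alone. The neuron list was higher as well (0.47, percentile 98.5), with 8 of 11 genes called higher in replicate 2, among them Mir128-1 and Mir137, and 2 called lower, Mir138-1 and Mir138-2 (10 adjusted over the list alone). All but 3 of its measured genes are multi-copy, and over those 3 the percentile was 88.0. The choroid plexus and ciliated cell list, at 0.95, was just past the limit (percentile 97.86), with Mir204 and Mir34b called 3.55-fold and 3.98-fold higher in replicate 2, Mir449a called 1.54-fold higher in replicate 1, and Mir34c at a ratio of 1.06 that was not called (3 adjusted over the list alone). Its position was lost with a mean count of at least 100 (percentile 58.2) and with no filter on low counts (78.3).

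The astrocyte list was higher in replicate 1, with a median log2 ratio of -0.83, below all random lists, and 7 of 10 genes called in that direction, among them Mir31, Mir29c (3.005-fold) and Mir22 (1.83-fold). Mir27a, at 2.06-fold, was called higher in replicate 2, and 8 genes passed when adjusted over the list alone. The erythroid list was also higher in replicate 1 (median log2 ratio -0.998, percentile 0.765), with all 3 measured genes, Mir451a, Mir144 and Mir486, called higher there (3 adjusted over the list alone). Both lists were thus lower in replicate 2, in which the neuron and epithelial lists were higher.

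The other lists lay inside the central 95% at the settings used throughout, but the oligodendrocyte list moved outside with a mean count of at least 100 (-0.59, percentile 1.885), and the muscle, liver and endocrine list did with no filter on low counts (-0.80, percentile 1.80). Their median log2 ratios were -0.37 for oligodendrocytes (2 genes called higher in replicate 1 and 1 in replicate 2, of 4), -0.12 for activity-regulated miRNAs (2 and 1 of 4), 0.17 for microglia and leukocytes (1 and 2 of 5), 0.32 for the vascular list (1 and 3 of 4), -0.56 for the Hox clusters (1 and 0 of 3) and 0.21 for muscle, liver and endocrine miRNAs (1 and 1 of 3). The let-7 family was at -0.21 (percentile 3.66), with 10 of 12 genes called higher in replicate 1 and 1 in replicate 2. The Dlk1-Dio3 cluster was at 0.03 (17 and 22 of 49), the Sfmbt2 list at -0.10 (2 and 1 of 8), the mir-17-92 list at 0.43 (3 and 5 of 11) and the multi-copy list at -0.13 (20 and 16 of 43). Adjusted over the list alone, 3, 3, 3, 4, 1, 2, 11, 39, 1, 8 and 36 genes passed, in the same order of lists. The sign of several medians hung on the setting. The mir-17-92 list was at -0.28 with a mean count of at least 100, where the microglia list was at -0.07, and with no filter on low counts the microglia list was at -0.31 and the vascular list at -0.05. The Dlk1-Dio3 cluster changed sign with scaling (-0.01 under TMM, -0.04 without the most abundant gene). The pluripotency list had no gene with enough reads for a ratio.

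**Figure D4:**
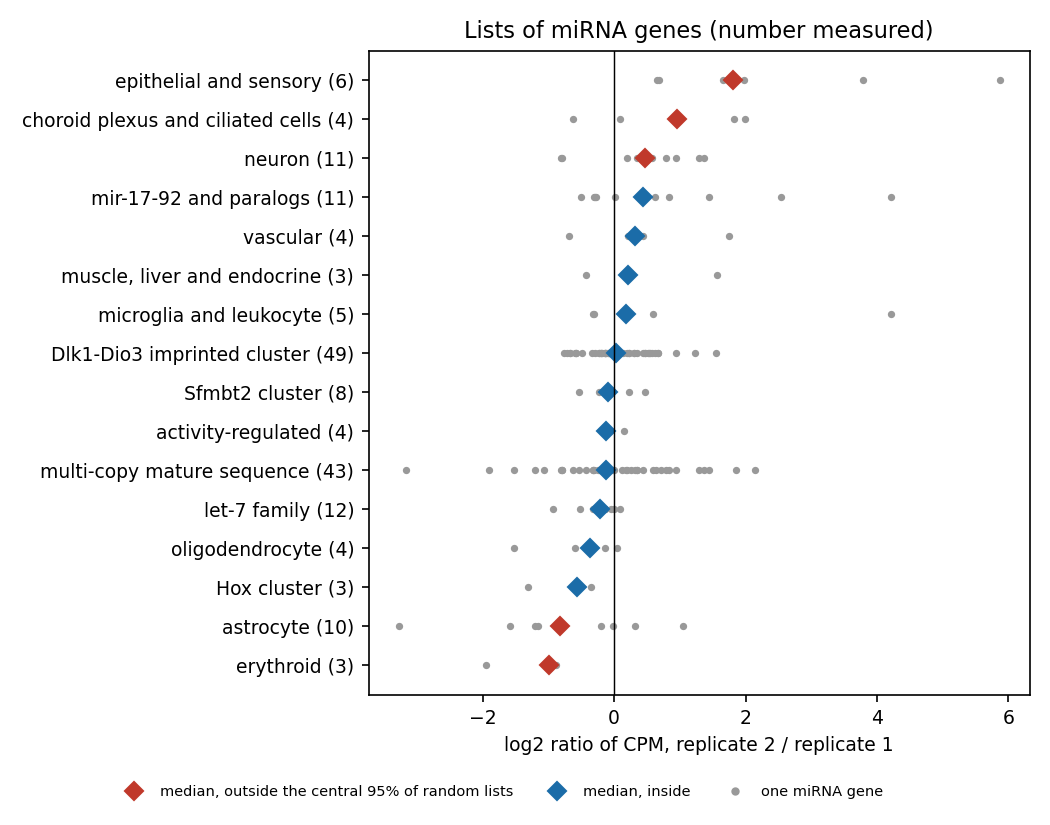
Log2 ratio of CPM, replicate 2 over replicate 1 (x axis), of each measured member (points) and its median (diamonds) for 16 lists of miRNA genes, with the number measured in parentheses. Red diamonds mark the 5 lists outside the central 95% of random lists: epithelial and sensory (1.81), choroid plexus and ciliated cells (0.95) and neuron (0.47) to the right, astrocyte (-0.83) and erythroid (-0.998) to the left.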

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

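The tests of counting noise, of the size of a linear GC trend, of Mir182 and Mir183 against other epithelial miRNAs, of depth, of scarcity, of multi-copy genes without members of other tissues and of neighbours outside the Dlk1-Dio3 cluster were chosen after the results were seen. With 1 group, no biological explanation that the design names was tested.

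Reads outside the main counts were summed over many places, so the limit for a count of 0, which holds for a single gene, does not apply to these totals. Reads with several equally good places numbered 3734600 in replicate 1 and 4807740 in replicate 2, more than the reads assigned to miRNA genes. Reads placed once on no annotated miRNA gene numbered 359942 and 492263. Antisense reads at miRNA genes with no miRNA gene on the opposite strand numbered 102 and 108. The other antisense reads, 225467 and 260829, lay at the 64 genes with a miRNA gene opposite. Of genes without such a partner, 6 had more than 3 antisense reads in both libraries, with Mir3083 (26 and 34) at the head.

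Some multi-copy miRNA genes, such as those of Mir124a and Mir9-2, had low counts, although the list as a whole had 41 of 56 genes detected. A candidate explanation is that they lost the reads fitting several genes, which the count table keeps apart. Genes of the multi-copy list shared in both the 5′ and the 3′ part (17) had a lower median log2(CPM + 1) than the other 39. The differences were -3.76 in replicate 1 and -4.76 in replicate 2, past the difference of 3 set beforehand. The 17 include the Mir124a genes and Mir9-2, named above for their low counts, so the contrast is not independent of the pattern. It was not computed without them. Without muscle and vascular miRNAs, which may be scarce in brain for their own reasons, the differences were -1.71 and -2.31, short of that bound. The other genes of the list are multi-copy too and can lose reads in the same way, so the contrast cannot decide. How far the reads kept apart account for the low counts stays open. That the miRNAs are scarce in the tissue could not be excluded either: reads with several places came to 1275420 per 1000000 assigned reads at the least, which leaves room for them but does not say whose reads they are.

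Genes of the choroid plexus list and in introns of Htr2c, a gene strongly expressed in choroid plexus epithelium, had a median log2 ratio of 1.99 over 9 genes. Of these, 7 were called higher in replicate 2, Mir449a was called lower and Mir34c was not called. In introns of Htr2c lie 5 of the 9, taken up after the values of Mir1264, Mir1298 and Mir448 were seen. The median and the number called are therefore partly set by that choice. The list written beforehand was at 0.95 alone. Counting noise is argued against, for the 7 genes called higher, only by the exact binomial test that called them, adjusted over all 474 genes tested. The median adjusted p of that test, 1.03e-11, is over all 9 and takes no account of direction. GC content was that of the whole hairpin. Removing its trend kept 100.1% of the median but moved no gene by more than 0.0111 and so tested nothing. The bound on what a linear trend over the 390 other genes could give was 0.0229 in log2 ratio. This argues against a linear trend on hairpin GC content only. The GC content of the sequenced reads was not examined, so a trend on it stays open. Choroid plexus tissue taken along in replicate 2 may be a source, but the 4 usable genes whose values had not been seen when its bounds of 0 and 1 were set had a median log2 ratio of 0.69, between them. Mir764 and Mir1912 (log2 ratios 1.30 and 2.42, the latter with 0 reads in replicate 1) lie in introns of Htr2c like Mir1298 and Mir448, which prompted the pattern, and are not independent of these, while Mir34c and Mir449a were at 0.08 and -0.62. Whether the same tissue could be the source of Mir182 and Mir183 stays open: the median of the epithelial mir-200 family lay lower (difference in log2 ratio -4.14), but of its 5 genes Mir200a (3.92-fold), Mir200b (3.15-fold) and Mir429 (1.58-fold) were called higher in replicate 2 too, Mir200c (1.61-fold) was not called, Mir141 had 8 and 4 reads and was not called, and Mir96 of the cluster had 0 and 5 reads.

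The libraries differed by more than counting noise, and a duplicate deposit or a difference of depth alone was argued against by a chi-square of 390 times its degrees of freedom. Sequence-dependent library preparation predicts a smaller difference in log2 ratio between genes of the same number at different places. Such a difference was found (136 pairs, mean 0.53 against 0.78 for abundance-matched pairs, one-sided permutation p = 0.0019). Letters were ignored, so pairs among the Mirlet7 genes, with log2 ratios from -0.52 to 0.09, are included. The value without them was not computed. Reads fitting several genes equally well were not counted, so counted reads may come from parts that differ between copies. That such genes vary apart in transcription was assumed, not tested. Different amounts of the primary transcripts, by animal or by dissection, are likewise consistent with the smaller difference between unlike neighbours (359 pairs, 0.58 against 0.83, one-sided permutation p = 0.0103). Of these pairs, 290 involve the Dlk1-Dio3 cluster, and for the other 69 the difference went the same way (0.79 against 0.90) with a permutation p of 0.2275, so the relation was not shown outside that cluster; whether pairs inside and outside it differ was not tested. Both explanations stay open.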

How the results depend on the processing

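The removal of the GC trend and the thinning of replicate 2 were chosen after the data were seen. Of the main results and the list ratios, 183 values under an alternative were labelled unchanged, and 14 were not. A list ratio was unchanged if it kept its side of the central 95% limits. A count was unchanged within 1.5-fold of the main one, and other values within their spread. Scaling adds the same constant to every log2 ratio, so list percentiles and the SD of the ratio could not change under it. The GC correction moved no gene by more than 0.0111. The 183 therefore overstate stability. Causes were not tested unless stated. With a mean count of at least 100, Pearson's r was 0.955, 3 lists lay outside the central 95%, the choroid plexus list fell inside (median log2 ratio 0.082) and the oligodendrocyte list moved outside (-0.59); the erythroid, epithelial and Hox cluster lists then had too few genes for a value. With no filter on low counts, r was 0.980, the SD of the log2 ratio 1.14 and the choroid plexus list fell inside (0.18). The muscle, liver and endocrine list then reversed to -0.80 and lay outside, on genes near the floor. Unfiltered values include ratios against the floor that point the wrong way, such as that of Mir449c in the choroid plexus list (2 and 0 reads, log2 ratio 0.27). A pseudocount of 0.1 gave r = 0.967. Requiring at least a 2-fold ratio left 80 differing genes by its construction, 48 higher in replicate 2 and 32 higher in replicate 1. Without multi-copy genes the neuron list fell inside at an equal median (0.47), since 3 genes remained, and the oligodendrocyte list had no ratio. Counts without strand raised the share of the 10 most abundant genes to 60.5%, because reads where miRNA genes overlap on opposite strands are then ambiguous. They left the erythroid and oligodendrocyte lists without a ratio, and put 11 lists above the upper limit of random lists (13 with strand). Detected genes numbered 475 with at least 3 reads, 459 with at least 1 CPM and 349 without strand, against 376. Leaving out either replicate gave 387 to 419 detected genes, a share of 57.4% to 57.8%, 17 to 18 of the first 20 genes and 13 to 14 lists above the upper limit. Scaling moved the share of differing genes that were higher in replicate 2 from 54.5% to 50.4% (TMM) and 47.0% (without the most abundant gene). Without multi-copy genes, or with no filter, the mir-17-92 list fell to 0.01; sign changes of medians inside the central 95% are given with the list ratios. With replicate 2 thinned to the depth of replicate 1, 253 genes differed. The coefficient of variation ranged from 0.372 to 0.404, within its spread over genes (bootstrap SD 0.0271). Depth limits genes under about 10 reads. No paired analysis was possible because there is 1 group.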

Other observations

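Of 7 miRNA genes annotated in the introns of Htr2c, on the plus strand of chromosome X, 5 were called higher in replicate 2 by the exact read test (chosen after their values were seen). Mir1298 had 295 and 6497 reads in replicates 1 and 2, Mir1264 46 and 311, Mir448 32 and 380, Mir764 30 and 92, and Mir1912 0 and 20. The ratio of Mir1264 was 5.43-fold (exact 95% interval 3.98 to 7.58) and that of Mir764 2.46-fold (1.62 to 3.86). Gm22650 had 4 and 14 reads, and its ratio of 2.81-fold had an interval that included equality (0.883 to 11.7). Gm24627 had 0 reads in both libraries.

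Counts of some copies of a miRNA lay far apart and those of others close together (examples chosen after their values were seen). Mir181a-1 was at 597 ± 51.9 CPM and Mir181a-2 at 14.0 ± 4.30 CPM, Mir219a-2 at 2178 ± 1486 CPM and Mir219a-1 at 10.4 ± 0.742 CPM, and Mir181b-2 at 1707 ± 254 CPM and Mir181b-1 at 17.8 ± 5.32 CPM (SD, n = 2). Mir26a-1 and Mir26a-2 were at 17.3 ± 13.9 and 14.8 ± 5.03 CPM, and Mir138-1 and Mir138-2 at 4780 ± 1808 and 3160 ± 1229 CPM. Which part of a hairpin the counted reads came from was not analysed here.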
